A study of Drosophila melanogaster with 3 samples.

How the data were processed

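Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, aged 0 to 16 hours. The flies carried a transgene for CG18262 with green fluorescent protein (GFP) fused to its C-terminus, and an antibody against GFP pulled down the fusion protein with its DNA, per the labels. The labels number 3 biological replicates with 1 technical replicate each, and give a size range of 200 to 800 bp. All 3 samples formed 1 group, so no groups were compared.

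For each replicate the authors deposited a list of peaks on the dm6 assembly, derived from that replicate's alignments and 1 control file shared by the replicates, per the labels' file listings. They also deposited a list called on the pooled replicates, and a list thresholded by the irreproducible discovery rate (IDR), a method that keeps peaks ranked alike in replicates. The aligner, the peak caller and their versions are not given in the sources used here. Each list gives a peak's start, end, summit, signal value and −log10 q-value. The signal value is the authors', on a scale that was not stated, and it was used only to rank or describe peaks within 1 list. The deposited −log10 q-value was at its maximum for all 8529 thresholded peaks, so it could not rank them. The read depth is unknown, because no read counts were analysed here. The control alignments and an untagged line were also not analysed here. Without them, signal that any antibody would give at open promoters cannot be separated from signal of the fusion protein.

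Each replicate list and the pooled list held exactly 30000 peaks, so list length carried no information on depth or on the number of bound sites. The thresholded list was found to hold exactly the 8529 pooled peaks of the highest signal value, and 21471 pooled peaks lay below it. It was therefore derived from the same reads as the replicate lists and was not an independent check of them. Median peak widths were 444, 456 and 496 bp in replicates 1 to 3, 484 bp in the pooled list and 404 bp in the thresholded list. No peak was identical between any pair of replicate lists. In the thresholded list 346 peaks shared a region with another peak and 4 summits lay outside their peak, and all were kept.

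Positions were compared with the Ensembl release 115 annotation of BDGP6.54 and the RefSeq sequence of the same assembly. Peaks on arms 2L, 2R, 3L, 3R, 4 and X were analysed. Coordinates are 1-based. For the replicates, the 8529 strongest peaks by signal value were used, of which 8505, 8507 and 8529 lay on these arms in replicates 1, 2 and 3. A peak counted as matched in another list when summits lay within 100 bp. A promoter peak had its summit within 500 bp of a start site of a protein-coding gene, and a gene with such a peak was called bound. Other summits were placed in 5' UTR, coding sequence (CDS), 3' UTR, non-coding exon, intron or intergenic sequence, in this order. Within the summits outside promoters, and within those in introns or intergenic sequence, shares were compared in the same way with those of shifted summits.

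Chance levels came from circular shifts of the summits within each arm, 100 for matching and 1000 for locations. The permutation p from shifts was two-sided and could not fall below 9.990e-04. Shares have exact Clopper-Pearson 95% intervals, and densities per Mb have exact Poisson intervals. Both cover counting error only. Gene lists and the X chromosome were tested with two-sided Fisher's exact tests, and p-values over the 25 gene lists were adjusted by the Benjamini-Hochberg method. Known sequences were searched on both strands in the 101 bp around each summit and in a window of the same length centred 300 bp to the lower-coordinate side. Shares were compared with exact McNemar tests, adjusted over the 15 sequences. The plan named the mean of both sides as the comparison and the lower-coordinate side as the test. The lower-coordinate side is reported, and the other side was an alternative. Sequences of 8 bases were ranked on arms 2L, 2R and X, and the 10 best were tested on 3L, 3R and 4. The median signal of promoter peaks was compared with that of other peaks by a permutation test with 100000 resamples. Neighbouring genes can share a peak and neighbouring peaks are not independent, so these p-values treat as separate some items that are not.

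The gene lists, the known sequences, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 25 protein-coding genes at the strongest promoter peaks matched in all 3 replicate lists, the 5 strongest peaks outside promoters, the 3 strongest promoter peaks on the X chromosome, the 3 bound members of each gene list with the strongest peaks, CG18262, and the eye colour gene w. Of the genes named by this rule, 1 is not reported here. Of the listed symbols, nos, Dpt, rye, calypso and TfIIIC220 matched no gene in the annotation, and h was matched as hry. The symbols msh and Dr matched the same gene, so the 17 dorsoventral symbols gave 16 genes. The roX genes do not code for protein and were not counted.

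The alternatives were the stronger part of the thresholded list (4264 peaks), the 7571 thresholded peaks matched in all 3 replicate lists, each replicate alone, leaving out each replicate, other distances for matches and promoters, other backgrounds of genes and start sites, and other sequence windows. Without a replicate, the peaks were those among the strongest of both remaining lists, with summit and signal taken from the lower-numbered list. Merging summits within 500 bp and leaving out the 500 strongest peaks were added after seeing the data.

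The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. They were tested on simulated data first. For 8529 simulated peaks, a shared share of 60.0% came back as 60.4%, and a promoter share of 38.0% came back as 38.0%. Of 20 random peak lists, 5% passed a permutation p of 0.05 for the promoter share. A sequence planted to reach 20.1% of 2000 peaks was found in 20.2%, and 0 of the 14 other sequences were called. The planted 8-base sequence ranked at the top. A list of 40 genes bound at 4-fold odds was called in 86% of 50 simulations, and 0.167% of 1200 lists without a difference were called. Of 100 simulated lists without a difference in signal, 4% reached a permutation p of 0.05. The comparison with windows matched on base composition was tested in this way only after its use, and a sequence made to occur in 2.43% of 8529 windows was called and 0 of the 14 others were.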

Results

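The data were 3 replicate ChIP-seq peak lists for CG18262 fused to GFP in 0 to 16 hour embryos, a list from the pooled replicates, and the authors' IDR-thresholded list of 8529 peaks. The labels describe the experiment as transcription factor ChIP-seq, so the question was where in the genome its peaks lay. The tagged gene, CG18262 (FBgn0030012), lies on X from 8152948 to 8154533 on the plus strand. All coordinates are on dm6. Values for the thresholded list have no replicates of their own, and for some of them the same value in the 3 replicate lists is given too.

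Peaks lay near start sites of genes more often than shifted summits did. As the control alignments and an untagged line were not analysed, signal that any antibody would give at open promoters cannot be separated from this excess. Of the 8529 peaks, 3223 (37.8%, 95% interval 36.8 to 38.8) had their summit within 500 bp of a start site of a protein-coding gene, compared with 11.4% for shifted summits, a 3.31-fold excess. Among the strongest such peaks were those of Mkp3, a phosphatase of the MAP kinase pathway, of px, which acts in wing vein patterning, of Art3, a protein arginine methyltransferase, of Chro, a chromatin protein of interbands, of Ugalt, a UDP-galactose transporter, and of ph-p, a Polycomb group gene. The promoter share in the replicates was 38.9% ± 0.665 (SD, n = 3), and the permutation p from 1000 shifts was 9.990e-04, the smallest they can give. With promoters limited to 200 bp the share was 25.1%, compared with 5.12% for shifted summits.

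The strongest thresholded peak lay on 2L with its summit at 12011321, and the peak matched to it ranked 1 in each replicate list. It lay in intergenic sequence 2943 bp from the nearest protein-coding start site, which belongs to Rh5, a rhodopsin gene. In the thresholded list the peak spanned 12010061 to 12012658 and its signal value was 31193. The strongest promoter peak had its summit on 3L at 19086807, 381 bp from a start site of Mkp3 (FBgn0036844, 19066155 to 19086426, minus strand), with a signal value of 12299. The peak at px (FBgn0003175) followed, on 2R at 22514304, 205 bp from a start site within the gene. The peak on 3R at 15229536 lay between Art3 and mRpS10, a gene for a mitochondrial ribosomal protein, 128 bp from the start of Art3. Those at Fkbp14, mRpL41 and Chro ranked 9, 10 and 12. The other genes at the strongest promoter peaks were CG18549, CG14100, CG1888, CG11309, CG3961, CG5611, CG13921, CG13390, CG1635, Ugalt, RluA-1, C1GalTA, Tina-1, E23, ph-p, PNPase, a mitochondrial exoribonuclease, msi, an RNA-binding protein of neural stem cells, CLIP-190, which binds microtubule ends, and gish, a casein kinase. These 25 genes ranked between 2 and 39 in the thresholded list, and their ranks in the replicate lists lay between 2 and 66. Outside promoters, the strongest peaks after the one near Rh5 lay in an intron of ush, a transcriptional cofactor, 1391 bp from the start of cbt, in an intron of CG11050, in intergenic sequence 3760 bp from the start site of CG31668, and in an intron of Trl, the gene of GAGA factor, on 3L at 14759521.

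Promoter peaks made up a larger part of the strongest peaks. The share was 60.0% (49.7 to 69.7) for the 100 strongest peaks, 52.5% (47.5 to 57.5) for the next 400 and 40.2% (35.9 to 44.6) for the 500 after those. It was 38.3% (35.3 to 41.4) for ranks 1001 to 2000, 34.1% (32.0 to 36.2) for ranks 2001 to 4000 and 37.3% (35.9 to 38.7) for ranks 4001 to 8529. The median signal value was nonetheless close, at 508.9 for promoter peaks and 503.0 for the others, a difference of 5.85 (permutation p = 0.557). This comparison depended on the peak set, and promoter peaks were stronger by 133.1 among the stronger part of the list (permutation p = 1.000e-05, the smallest 100000 resamples can give). It also passed without replicate 1, with a difference of 23.2 (permutation p = 1.000e-05), and without replicate 2, with 11.5 (permutation p = 0.00237). The same held for peaks matched in all 3 lists (43.1, permutation p = 3.000e-04), replicate 3 alone (18.7, permutation p = 1.600e-04) and merged summits (27.2, permutation p = 0.0217). The comparison missed the threshold in replicates 1 and 2 alone (−4.26 and 3.03) and without replicate 3 (4.02). It also missed it without the 500 strongest peaks (−7.27) and with promoters of 1000 bp (12.2). With promoters limited to 200 bp the direction turned, and the difference was −32.0 (permutation p = 0.00314).

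Genes for cytosolic ribosomal proteins had the highest bound share of the 25 lists. Of 86, 76 (88.4%, 79.7 to 94.3) were bound, compared with 26.4% of all other protein-coding genes, an odds ratio of 21.2 (Fisher's exact test, adjusted p = 7.094e-32). In replicates 1 to 3, 81.4%, 83.7% and 86.0% were bound. The odds ratio was 10.4, 8.53 and 9.26 without replicates 1, 2 and 3, and 7.12 with the stronger part of the list, and it rose to 35.7 among isolated genes and 42.7 within classes of gene length. The strongest peak among them was at RpL34b (rank 517), followed by RpS27 (rank 799), so they were numerous rather than at the top of the list. Over all genes, 3728 of 13945 (26.7%) were bound.

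Genes for mitochondrial ribosomal proteins were bound in 38 of 73 cases (52.1%, 40.04 to 63.9, adjusted p = 1.691e-05 by Fisher's exact test), with the strongest peaks at mRpS10 (rank 6), mRpL41 (10) and mRpS23 (45). Among the 13 of them with no other gene's start site within 1000 bp, 2 were bound, an odds ratio of 0.942 (exact p = 1), and among the 60 with such a neighbour 36 were bound, an odds ratio of 2.20 (exact p = 0.00333). The difference between these odds ratios was not shown (exact p = 0.4996).

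Genes for proteins that organise or regulate chromatin were also bound often. Among architectural and insulator proteins 13 of 21 were bound (61.9%, 38.4 to 81.9, adjusted p = 0.00207, Fisher's exact test), led by Chro, Cp190 (rank 122), a cofactor of insulator proteins, and M1BP (rank 227), which binds promoters. Among genes with no other start site within 1000 bp, 2 of 7 were bound, and the call was lost with an odds ratio of 2.07 in place of 4.47. The peak at Chro also lay within 500 bp of a start site of Ssl1. Dref shared its peak with RpL13 and Cap-H2 with MED7, so these peaks counted in different lists. In the Polycomb and Trithorax group 17 of 29 were bound (58.6%, 38.9 to 76.5, adjusted p = 0.00128, Fisher's exact test), led by ph-p (rank 38), E(z), the histone H3 methyltransferase (rank 207), and the chromatin remodeller brm (rank 217). This group missed the threshold without replicate 1 and without replicate 2, with odds ratios of 2.14 and 2.47 in place of 3.90. Of 32 cell cycle genes 19 were bound (59.4%, 40.6 to 76.3, adjusted p = 5.275e-04, Fisher's exact test), led by RnrS, a ribonucleotide reductase subunit (rank 564), Dp, the partner of E2F (1077), and Mcm2, a subunit of the replicative helicase (1313). This call was lost with promoters limited to 200 bp and among isolated genes, with odds ratios of 2.03 and 2.60 in place of 4.02. Of 47 genes of the basal transcription machinery 20 were bound (42.6%, 28.3 to 57.8, adjusted p = 0.0381, Fisher's exact test), led by Taf2, Taf5 and MED17. That call was made in 1 of 3 replicates and was lost without any 1 replicate. The odds ratios were then 1.75 to 2.09, compared with 2.04 with all replicates. Of the isolated genes of this list 3 of 13 were bound, an odds ratio of 1.56 (Fisher's exact test, p = 0.454). Of those with another start site within 1000 bp 17 of 34 were, compared with 40.7% of other such genes (odds ratio 1.46, Fisher's exact test, p = 0.296).

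Lists of chemosensory receptor, cuticle, antimicrobial peptide, chorion and testis genes were bound rarely. Expression was not analysed, so signal that any antibody would give at open promoters cannot be separated from this pattern either. None of 60 odorant receptors and none of 60 gustatory receptors was bound (upper limit of the 95% interval 5.96%, adjusted p = 5.209e-08 for each by Fisher's exact test). Of 90 cuticle protein genes 2 were bound (2.22%, adjusted p = 4.038e-09, Fisher's exact test), Cpr67Fa1 and Cpr65Ea. No antimicrobial peptide gene of 20 (adjusted p = 0.00934) and no chorion, vitelline membrane or yolk gene of 18 (adjusted p = 0.0135) was bound, and of 23 testis-enriched genes 1 was, nht (adjusted p = 0.0324; Fisher's exact tests). These 3 calls were lost without replicate 2, and the testis call also without replicate 3, with odds ratios of 0, 0, 0.183 and 0.169. All 3 were also lost within classes of gene length (odds ratios 0, 0 and 0.189) and among isolated genes (0, 0 and 0.345), and the antimicrobial and chorion calls with promoters limited to 200 bp (0 for both).

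None of the 111 replication-dependent histone genes was bound (adjusted p = 2.245e-14, Fisher's exact test). Among isolated genes 0 of 27 were bound and the call was lost. No list had a summit in their cluster on 2L from 21416953 to 21541681, where 27.9 summits per list of 30000 would lie at the mean density. The cluster consists of near-identical copies, so reads there could be placed at several copies, and this absence is uncertain.

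For patterning genes and markers of single tissues no difference from other genes passed the threshold. Most of these genes were isolated, while the other genes also included those with close neighbours. Over all genes 16.2% of isolated ones were bound, and 40.8% of those with another start site within 1000 bp. Bound were 1 of 9 gap and terminal genes (bcd), 1 of 9 pair-rule genes (hry), 3 of 8 homeotic genes (Dfd, Antp and lab) and 6 of 16 dorsoventral genes, among them cact, Tl and rho (adjusted p = 0.548 for each). Of 14 segment polarity genes 5 were bound, with sgg at rank 281, nkd at 453 and fz at 5789 (adjusted p = 0.619, Fisher's exact test). Among isolated genes 5 of 13 segment polarity genes were bound, compared with 16.1% of others (odds ratio 3.25, Fisher's exact test, unadjusted p = 0.0456). For isolated dorsoventral genes the odds ratio was 2.89 (Fisher's exact test, unadjusted p = 0.0618), and neither call was made after adjustment. Other isolated odds ratios were homeotic 2.07, neural 1.30, gap 0.740, pair-rule 0.647, muscle 0.740, and hemocyte and fat body 0.431. Of 21 neural genes 5 were bound (adjusted p = 1, Fisher's exact test), with elav, a pan-neuronal RNA-binding protein, at rank 88, and grh and scrt next. Of 17 muscle structural genes 3 were bound, Tm1, Act87E and sls (adjusted p = 0.635, Fisher's exact test), and of 16 hemocyte and fat body genes 1 was, vkg (adjusted p = 0.155). The lists of the proteasome (16 of 44, led by Rpn3, Rpn11 and Rpn5, adjusted p = 0.279), heat shock genes (7 of 17, led by Hsp27, Hsp26 and Hsp83, adjusted p = 0.279), RNA polymerase II (5 of 13, led by Polr2B, Polr2H and Polr2F, adjusted p = 0.518) and dosage compensation (1 of 7, Sxl, adjusted p = 0.712) also missed the threshold, all by Fisher's exact test. RNA polymerase II passed it without replicate 1, with an odds ratio of 4.08 in place of 1.71, the proteasome with promoters limited to 200 bp (2.31 in place of 1.57), and the hemocyte and fat body list, as bound less often, in replicate 2 alone (0 bound). Several of these lists are small, and a difference of moderate size may have been missed. How large a difference small lists could show was not simulated. In total 13 of 25 lists passed, 6 bound more often and 7 less often, and without replicate 2 the number was 8. With the stronger part of the list 7 passed, and the calls lost were those of the Polycomb and Trithorax group, cell cycle, basal transcription, antimicrobial, chorion and testis lists.

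**Figure D1:**
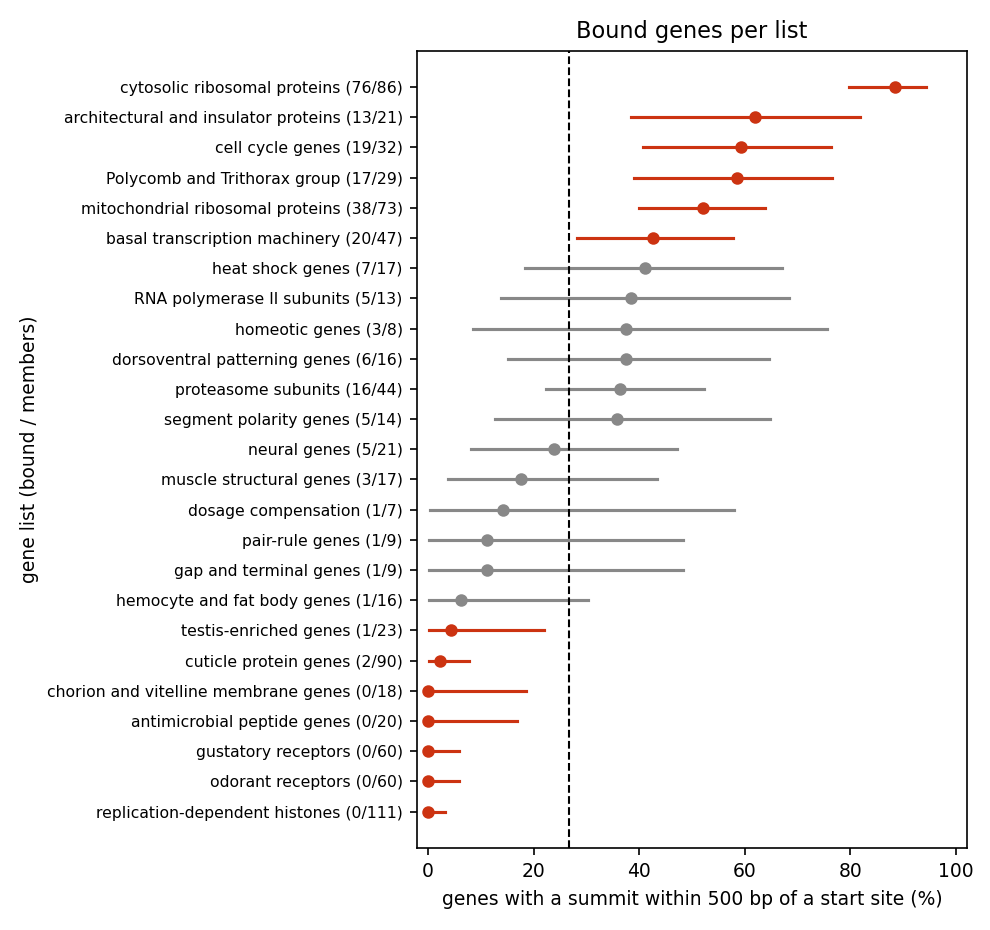
Share of the genes of each list (percent, horizontal axis) with a thresholded summit within 500 bp of a start site, with exact 95% intervals. Bound genes and list size stand beside each name, red points passed an adjusted p of 0.05, and the dashed line is the 26.7% of all protein-coding genes. Cytosolic ribosomal protein genes stand highest at 88.4%.

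Away from promoters, summits were rare in coding sequence and in 3' UTRs. Only 15 of 8529 summits (0.176%) were classed as coding sequence, compared with 13.8% for shifted summits, and the share in the replicates was 0.157% ± 0.0181 (SD, n = 3; permutation p = 9.990e-04, the smallest possible). Over all summits, 3' UTRs held 0.891% compared with 4.52%, 5' UTRs outside promoters 0.457% compared with 0.785%, non-coding exons 1.82% compared with 1.57%, introns 38.4% compared with 39.9%, and intergenic sequence 20.4% compared with 28.0%. These classes exclude each other, so the excess at promoters and the losses from coding sequence and 3' UTRs move the other shares too. Further comparisons, chosen after the results were seen, were therefore made within parts of the summits. Among the 5306 summits outside promoters, coding sequence held 0.283% compared with 15.6% for shifted ones, and 3' UTRs 1.43% compared with 5.10%. Non-coding exons held 2.92% compared with 1.77%, and introns 61.8% compared with 45.0%, both raised in part by these losses. The permutation p was 9.990e-04 for each of these classes, the smallest possible. For intergenic sequence (32.8% and 31.6%, permutation p = 0.343) and 5' UTRs (0.735% and 0.886%, permutation p = 0.197) no difference was shown. Among the 5021 summits in introns or intergenic sequence, 65.3% lay in introns, compared with 58.8% for shifted ones (permutation p = 9.990e-04, the smallest possible), and in the replicates the share was 66.0% ± 0.462 (SD, n = 3).

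**Figure D2:**
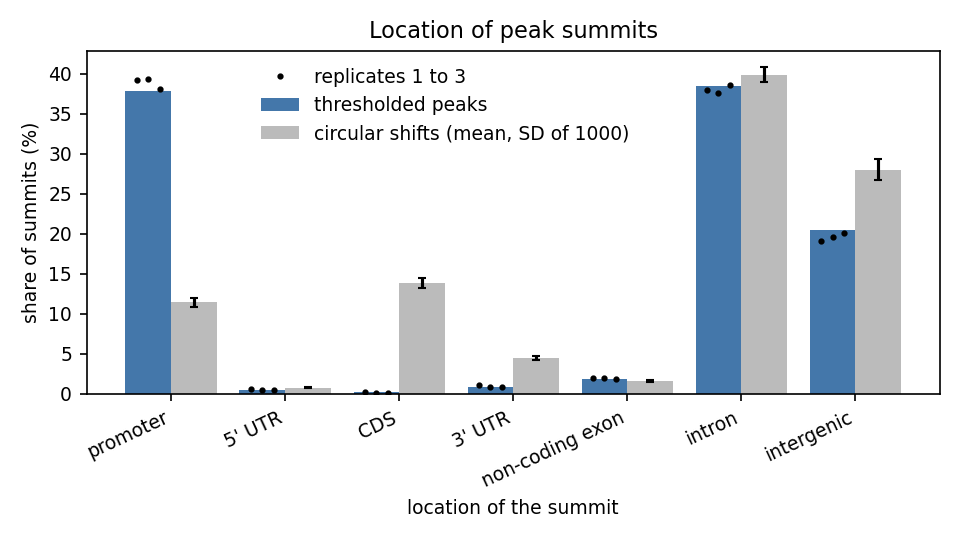
Share of summits (percent, vertical axis) in each kind of location. Blue bars are the 8529 thresholded peaks, black points the strongest peaks of replicates 1 to 3, and grey bars the mean of 1000 circular shifts with their SD. The classes exclude each other. Promoters held 37.8% of summits and coding sequence 0.176%.

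Peak density per Mb was lowest on arm 4, the smallest one, and among the large arms on 2R. It was 66.7 peaks per Mb on 2L, 56.7 on 2R, 69.4 on 3L, 61.2 on 3R and 66.6 on X, compared with 33.4 on arm 4 (exact Poisson interval 24.3 to 44.7, 45 peaks). In the replicates it was 57.6 ± 1.56 on 2R and 31.9 ± 3.93 on arm 4 (SD, n = 3). Density per Mb takes no account of gene number, so it does not show that genes on arm 4 were bound less often. Arm 4 had 45 peaks and 80 protein-coding genes, and 2R 1433 peaks and 2852 genes. The share of peaks at promoters was 44.4% on arm 4, and from 32.8% (3L) to 43.1% (2R) on the others. On X, 588 of 2196 genes (26.8%) were bound, and on 2L, 2R, 3L and 3R together 3121 of 11669 (26.7%), an odds ratio of 1.00 (Fisher's exact test, p = 0.979). The strongest promoter peaks on X were at Ugalt (rank 13, summit 2703896), ph-p (rank 38, summit 2137335) and pdgy (rank 85, summit 14951029). The odds ratio for X was 0.880 without replicate 1 (exact p = 0.0254), 0.889 without replicate 3 (exact p = 0.0434) and 0.935 without replicate 2 (exact p = 0.268). With the stronger part of the list it was 0.831 (exact p = 0.00555). With promoters limited to 200 bp it was 0.799 (exact p = 3.475e-04), and with promoters of 1000 bp 1.03 (exact p = 0.528). Among isolated genes it was 1.19 (exact p = 0.0301), so its direction depended on the peaks and genes used.

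Summits lay in stretches rich in A and T. The promoter-associated DRE sequence TATCGATA, the target of DREF, occurred within 50 bp of 1.43% of summits and in 0.528% of flanking windows (adjusted p = 1.668e-09, exact McNemar test), and in promoter peaks in 3.29% and 1.18%. The TATA box TATAWAAR occurred at 10.9% of summits and in 3.83% of flanks (adjusted p = 4.743e-69), and the homeodomain core TAATTA at 12.3% and in 5.64% (adjusted p = 1.284e-51; exact McNemar tests). Also more frequent at summits were Ohler motif 6 of core promoters (4.73% and 2.19%, adjusted p = 5.356e-19), the Initiator (26.5% and 22.3%, adjusted p = 6.416e-10), the Su(Hw) insulator core (0.832% and 0.352%, adjusted p = 8.637e-05) and the Twist site CATATG (3.95% and 2.86%, adjusted p = 1.386e-04), by exact McNemar tests. Less frequent were the GAGA factor and CLAMP site GAGAGAG (0.985% and 3.10%, adjusted p = 1.194e-22), the E-box CAGCTG (2.74% and 5.16%, adjusted p = 8.002e-16) and the Zelda site CAGGTAG (0.387% and 0.692%, adjusted p = 0.0132), by exact McNemar tests. Each of these 10 differences had the same direction in all 3 replicates. Several depended on the comparison with flanks. In a comparison chosen after the results were seen, with windows away from peaks that had the same G+C content and kind of location, the ratio was 1.03 for the TATA box, 0.954 for the homeodomain core, 1.02 for Ohler motif 6 and 0.951 for the Initiator, and none of them passed as more frequent at summits in any of 20 draws of windows. The Initiator passed as less frequent in 6 draws and the homeodomain core in 1. There CAGCTG was 1.52 times as frequent at summits and passed as more frequent in 20 draws, GAGAGAG 1.60 times and in 14 draws, and the Zelda site 1.33 times and in 0 draws. The DRE (3.43 times, in 20 draws), the Twist site (1.30 times, in 19) and the Su(Hw) core (1.77 times, in 17) kept their direction. The Zelda call was lost without replicate 1 (0.391% at summits and 0.616% in flanks), without replicate 2 (0.490% and 0.719%), in replicates 1 and 2 alone and outside promoters (0.452% and 0.660%). The DRE call was lost with the stronger part of the list (0.680% and 0.375%) and outside promoters (0.302% and 0.132%), where its ratios were 1.81 and 2.29 in place of 2.71. The Twist call was lost with the stronger part (3.73% and 2.98%) and in promoter peaks (3.04% and 2.45%). M1BP, Ohler motif 7, CAYCNCTA, CTCF and TCF sites missed the threshold, with adjusted p from 0.0929 to 1 by exact McNemar tests. Ohler motif 7 was more frequent than in flanks in promoter peaks (6.52% and 4.84%) and less frequent outside promoters (1.87% and 2.58%), and both differences passed. The CTCF core passed as less frequent without replicate 2 (1.80% and 2.55%), without replicate 3 (1.68% and 2.49%), with the stronger part (1.48% and 2.35%) and in wider windows (4.28% and 5.16%). Against the windows of the same G+C content the CTCF core was instead 2.60 times as frequent at summits, and passed in 20 of 20 draws. M1BP passed as more frequent against the other flank (0.504% and 0.258%), as did CAYCNCTA (1.79% and 1.31%).

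**Figure D3:**
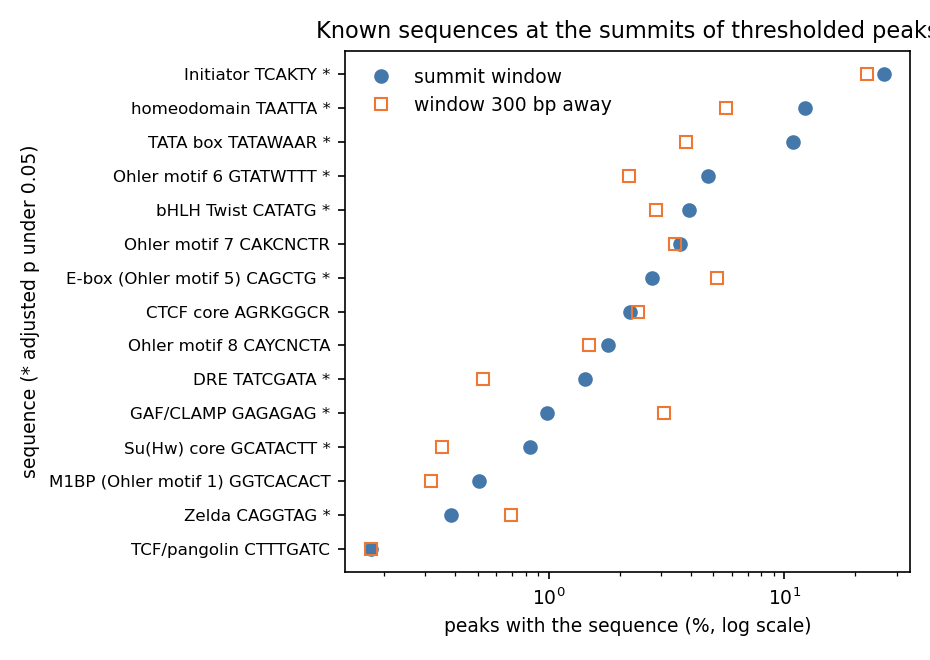
Share of the 8529 thresholded peaks (percent, horizontal log axis) with each sequence within 50 bp of the summit (blue points) and in the window 300 bp to the lower-coordinate side (orange squares). Stars mark adjusted p under 0.05. The label Ohler motif 8 stands for the searched sequence CAYCNCTA, which shares hits with the searched form of motif 7. No result is claimed for motif 8 itself. The TATA box occurred at 10.9% of summits and in 3.83% of flanks.

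All 10 sequences of 8 bases chosen on arms 2L, 2R and X consisted of A and T alone, and all 10 were more frequent at the 3959 summits of the held-out arms than in their flanks. For example TTTAAAAA occurred at 8.21% of summits and in 1.62% of flanks (adjusted p = 1.210e-44), AATAAATA at 8.08% and in 2.68%, and ATATTTTA at 7.45% and in 1.44% (adjusted p = 2.116e-39; exact McNemar tests). The largest adjusted p among the 10 was 6.760e-23. Against windows of the same G+C content the 10 were 1.04 to 1.28 times as frequent, and 4 of them passed as more frequent in at least 1 of 20 draws. Measured after these results were seen, the mean G+C content was 31.3% at summits and 44.1% in the flanks of the thresholded peaks. In the replicates it was 31.9% ± 1.04 and 43.9% ± 0.148 (SD, n = 3).

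No thresholded peak lay within 2000 bp of CG18262, nor did any peak of the pooled list or of replicates 1 and 3. The list of replicate 2 had 3 there, the best at rank 15296. At w (FBgn0003996, X, 2790599 to 2796466), the usual marker of fly transgenes, 3 thresholded peaks lay within 2000 bp, the best at rank 2928 with its summit at 2790129, and none had its summit inside the gene. In replicates 1 to 3 the best peak near w ranked 2687, 3178 and 3299.

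The replicates shared most of their strong peaks. Of the 8529 thresholded peaks, 7571 (88.8%, 88.1 to 89.4) had a summit within 100 bp in all 3 replicate lists, compared with 1.70% for shifted summits, and 5 had none in any list. Matches were found in 93.8% for replicate 1, 96.6% for replicate 2 and 97.0% for replicate 3. When only as many of each replicate's strongest peaks were used, 65.6% were matched in all 3. The share fell with signal, from 98.4% of the 853 strongest peaks to 73.9% of the 852 weakest. Between the strongest peaks of each pair of replicates the overlap was 74.9% ± 3.15 (SD over 3 pairs, which share replicates), with 74.9% for replicates 1 and 2, 71.8% for 1 and 3 and 78.1% for 2 and 3, compared with about 1.29% for shifted summits. Signal values at shared peaks were ordered alike, with Spearman's rho across peaks of 0.850, 0.805 and 0.844 for the same pairs. Peaks are not independent replicates, so no p is given for these. All these shares depended on the distance allowed, and within 50 bp 63.6% of thresholded peaks were matched in all 3 lists.

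**Figure D4:**
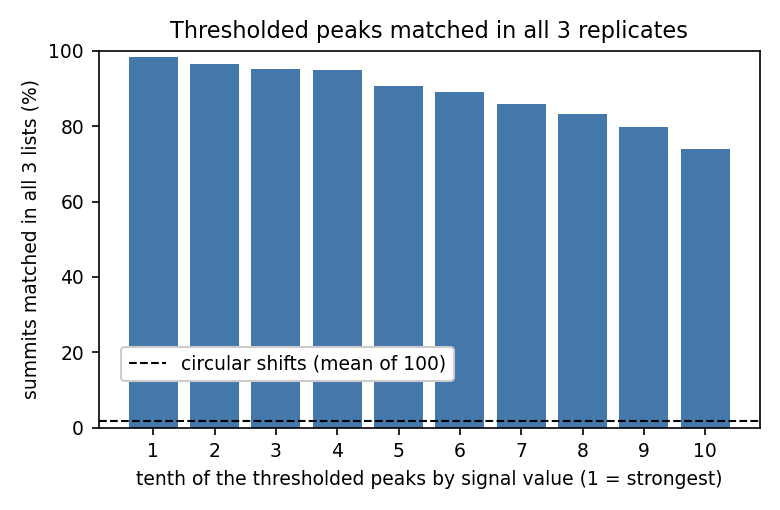
Share of thresholded peaks (percent, vertical axis) with a summit within 100 bp in all 3 replicate lists, for 10 classes of signal value from the strongest (1) to the weakest (10). The dashed line is the mean of 100 circular shifts over all thresholded peaks. The share falls from 98.4% to 73.9%.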

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

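Neither result in this part was planned, and both concern peaks that lie outside the thresholded list. The list of replicate 1 held 24 peaks on the mitochondrial genome, at ranks from 4 to 5856, and that of replicate 2 held 23, at ranks from 16 to 9227. The lists of replicate 3, of the pooled replicates and of the thresholded peaks held 0. These peaks took up 24 and 22 of the 8529 strongest places in replicates 1 and 2. Whether mitochondrial reads were treated differently in replicate 3 was not tested.

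The 21471 pooled peaks below the threshold were used in the report only to check single loci and to place windows away from peaks. Of these, 5416 (25.2%, 95% exact interval 24.6 to 25.8) had a summit within 100 bp in all 3 replicate lists, compared with 1.69% for shifted summits and at most 1.93% in any of 100 shifts. Of the matched ones 27.2% were promoter peaks, and of the others 21.7%. The replicates therefore shared many sites that the thresholded list leaves out.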

How the results depend on the processing

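Merging summits within 500 bp and leaving out the 500 strongest peaks were chosen after seeing the data, and all other settings before. The promoter share stayed above chance at the smallest possible permutation p in every setting, from 25.1% (within 200 bp) to 46.3% (within 1000 bp). In each setting 10 sequences of 8 bases were chosen anew and all 10 passed, but those shared with the 10 chosen with all data numbered from 1 (replicate 1 alone) to 9 (matched peaks). The number of known sequences that passed ranged from 9 to 14. Read depth limits what these lists can show to an unknown degree. The cause of the changes below was not tested.

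The share of thresholded peaks matched in all lists used was 63.6% within 50 bp, 97.0% within 250 bp, 97.4% with any overlap, 67.7% with an overlap of at least 50% of both peaks, and 91.1% to 94.0% without a replicate. The overlap between replicates was 85.8% for the 1000 strongest peaks, 79.9% for 5000, 55.9% for all, 61.2% within 50 bp, 82.6% within 250 bp, 83.2% with any overlap, 67.0% with 50% of both, and 71.8% to 78.1% without a replicate. Rank agreement was 0.867 as Pearson's r of log2 signal, and 0.805 to 0.850 without a replicate.

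The odds ratio of X genes fell below 1 for the stronger part of the list (0.831, exact p = 0.00555), replicates 1, 2 and 3 alone (0.902, 0.856 and 0.956), merged summits (0.990) and promoters of 200 bp (0.799, exact p = 3.475e-04), and was 0.880 to 0.935 without a replicate. It was 1.19 among isolated genes (exact p = 0.0301). The signal of promoter peaks minus that of others was 133.1 for the stronger part, 43.1 for matched peaks, 18.7 in replicate 3, 27.2 with merged summits and 4.02 to 23.2 without a replicate. It was −4.26 in replicate 1, −7.27 without the 500 strongest peaks and −32.0 with promoters of 200 bp (permutation p = 0.00314).

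Of 25 gene lists, 13 passed with all data, 7 with the stronger part, 8 to 12 without a replicate and 5 among isolated genes. The basal transcription call was lost under 12 of its alternatives, testis 7, chorion 6, antimicrobial 5, Polycomb 3 and cell cycle 3, and the architectural and histone calls among isolated genes only. Odds ratios changed direction as follows, in lists that missed the threshold before and after except the mitochondrial ribosomal proteins, at 0.942 among isolated genes. With the stronger part they were proteasome 0.552, segment polarity 0.921, dorsoventral 0.789, neural 1.30 and muscle 1.18. With matched peaks neural was 1.01. In replicate 1 alone, pair-rule was 1.37, neural 1.10 and dosage compensation 1.10. In replicate 2 alone, homeotic was 0.860 and neural 1.03, and in replicate 3 alone dorsoventral was 0.913. Leaving out a replicate gave dorsoventral 0.806 to 1.24 (0.932 without replicate 2), neural 1.09 to 1.49 (1.26 without replicate 2), gap genes 0.437 to 1.06 (highest without replicate 3), homeotic 0.532 to 2.43 (lowest without replicate 3), heat shock 0.866 to 1.55 (lowest without replicate 2) and segment polarity 0.953 without replicate 1. Among isolated genes neural was 1.30 and dosage compensation 1.73, within classes of gene length segment polarity was 0.993, and with promoters of 200 bp homeotic was 0.

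The known sequences that changed direction against flanks under some setting had missed the threshold with all data. At summits M1BP was in 0.211% of the stronger part and 0.399% in replicate 3. Ohler motif 7 was in 2.51% of the stronger part, 3.33% of matched peaks, 3.46% without replicate 2 and 1.87% outside promoters, where it passed as less frequent. It kept its direction without the other replicates (up to 3.62%), and passed as more frequent in promoter peaks (6.52%), in replicate 2 alone (4.03%) and in the wider windows (9.15%). The sequence CAYCNCTA was in 1.13% of the stronger part and 1.46% without replicate 1, keeping its direction without the others (up to 1.55%). It passed in the wider windows (4.35%) and against the other flank. M1BP passed in the wider windows (1.15%), in replicate 2 alone (0.635%) and against the other flank, and CTCF was in 2.36% of promoter peaks. The DRE and Twist calls were each lost under 2 of the alternatives, and the Zelda call under 5.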

Other observations

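Chosen after results were seen were the measurements in the opening paragraphs of this part, the tests of sequences against windows of matched base composition with their rule over 20 draws, the comparison of signal at ribosomal genes, and the comparison of genes with and without neighbours. The tests of coding sequence and of start site numbers at ribosomal genes were written before their results.

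Summits of promoter peaks lay mostly upstream of the start site. Of 1767 peaks with the start sites of just 1 gene within 1000 bp, 80.5% (95% exact interval 78.5 to 82.3) had their summit upstream of the nearest start site, and the median summit lay 167 bp upstream, with quartiles at 41 and 297 bp. The replicates gave 79.5% ± 5.26 upstream and a median of 161 bp ± 21.8 (SD, n = 3). Genes with another gene's start site within 1000 bp were bound more often than isolated genes. The counts were 2440 of 5985 (40.8%) and 1288 of 7960 (16.2%), an odds ratio of 3.57 (Fisher's exact test, p = 4.818e-231). A peak between close start sites makes the genes on both sides bound, so some of this excess follows from the definition. How much was not tested, and the p counts such a peak for each gene. In the Polycomb and Trithorax group the odds ratio was 15.6 among isolated genes (9 of 12 bound) and 1.29 among the others (8 of 17), a difference that missed the threshold once adjusted over 19 lists (exact p = 0.00422, adjusted p = 0.0801).

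Some genes that do not code for protein were also bound, counting only those at least 1000 bp from any protein-coding start site. Of 211 tRNA genes 31 were bound (14.7%) compared with 5.73% for shifted summits (permutation p = 0.001998, adjusted p = 0.004995). The share was 20.9% in replicate 1, 18.5% in replicate 2 and 8.53% in replicate 3, so its size was not stable. Of 27 snRNA genes of the spliceosome and related particles 7 were bound (25.9% compared with 5.95%, permutation test, adjusted p = 0.0133), and of 2331 other non-coding RNA genes 192 were (8.24% compared with 5.96%, permutation test, adjusted p = 0.004995). Pseudogenes were bound less often (2 of 190, 1.05% compared with 5.90%, permutation test, adjusted p = 0.0150). For snoRNA genes no difference was shown (6 of 184, 3.26% compared with 5.73%, permutation test, adjusted p = 0.421). Whether reads could be placed uniquely at these kinds of genes was not tested.

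Peaks were crowded in a few regions. The window on 3R from 16200001 to 16250000, which holds much of tara, had 27 thresholded peaks, and 24, 25 and 24 of the strongest peaks of replicates 1 to 3. The windows on 3L from 11400001 to 11450000 and from 18200001 to 18250000 had 25 each, with 0 promoter peaks in either. The mean was 3.19 peaks per window of 50000 bp, and the highest count in 1000 draws of uniform positions was 15. Uniform positions take no account of the excess at promoters or of differences between arms, so they set a low bar. Summits were not merged here, and 346 thresholded peaks shared a region with another, so 1 region can count more than 1 time. The window on 2R from 18650001 to 18700000, with Sik3 and edl, had 19 peaks, of which 7 were promoter peaks.

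Of the sequences that missed the threshold against flanks, several were more frequent at summits than in windows away from peaks with the same G+C content and kind of location, in 20 of 20 draws of such windows. The M1BP site was 4.20 times as frequent, the CTCF core 2.60 times, CAYCNCTA 2.17 times and Ohler motif 7 (CAKCNCTR) 1.94 times. As CAYCNCTA and CAKCNCTR share hits, their values are not separate results. The matched windows lay over 1000 bp from any pooled summit, so those in promoters belong to promoters without a peak.

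Summits were richer in A and T than their flanks, with lower G+C content at the summit in 6857 of 8529 peaks (80.4%, 79.5 to 81.2), and base composition is a candidate explanation for the differences in sequence. The windows of matched G+C content could not exclude it for the TATA box, 1.03 times as frequent at summits as in these windows, the homeodomain core (0.954), Ohler motif 6 (1.02), the Initiator (0.951), or the 8-base sequences, of which 0 of 10 were more frequent in at least 19 of 20 draws, 4 were in at least 1, and ATATTTTA was in 13 (1.28 times). The lower frequency of GAGAGAG, CAGCTG and the Zelda site was not seen against these windows, with ratios of 1.60, 1.52 and 1.33, and CAGCTG turned to higher in 20 of 20 draws and GAGAGAG in 14. G+C content as the whole cause is argued against for the DRE (3.43, higher in 20 of 20 draws, largest adjusted p = 4.175e-08, exact McNemar test). The Twist site met the rule of 19 draws narrowly (1.30, in 19, largest adjusted p = 0.107, exact McNemar test). It stays open, as does the Su(Hw) core (1.77, in 17). All draws used the same summits, so they are not repeated evidence, and only G+C content and kind of location were matched, not the order of bases. No biological explanation was tested, as the design has 1 group, and whether CG18262 itself reads any of these sequences is not shown.

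Few summits lay in coding sequence, and base composition could account for only part of this. Coding bases made up 17.0% of shifted summits, 4.75% of random windows with the same G+C content as the summits (SD over draws 0.222) and 0.469% of the summits themselves, so composition as the whole cause is argued against. Peaks over coding sequence whose summits fall in A/T-rich stretches beside it may contribute, since 8.23% of positions 300 bp from a summit were coding, 0.485 of the share of shifted summits. That lies between what this explanation and its absence predicted, so it stays open. No biological explanation was tested.

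Ribosomal protein genes were bound often, and genes with many start sites or close neighbours have more chances of a peak. Within strata of both counts the odds ratio was 15.6 for cytosolic (p = 4.661e-26) and 2.48 for mitochondrial ribosomal proteins (p = 1.764e-04, Mantel-Haenszel chi-square tests over genes), which argues against these counts as the whole cause. For the mitochondrial ones the odds ratio among isolated genes was nonetheless 0.942. Low-level signal that any antibody may give at highly active promoters stays open for the cytosolic ones: the median signal of their strongest promoter peaks differed from that of other bound genes by 64.9 (659.8 compared with 594.9, permutation p = 0.391), and a control from untagged flies was not analysed here. No biological explanation was tested.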
